A study of Solanum lycopersicum with 4 samples.

How the data were processed

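Transcripts of tomato (Solanum lycopersicum) floral apices and closed flower buds were measured by RNA sequencing in 4 libraries. Of these, 2 came from plants labelled MT, the usual abbreviation of the dwarf cultivar Micro-Tom, and 2 from plants labelled 156OE, which overexpress the microRNA miR156. Total RNA had been treated with DNase before cDNA synthesis, per the labels' protocols. The labels name RNA replicates of each genotype and do not say whether they came from separate plants, so p-values measure only the spread between these samples.

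The submitters' processing notes name Trimmomatic, HISAT2, Picard, SAMtools and Salmon, without versions or order, and the genome build and annotation are not given in the sources used here. The deposited tables are Salmon transcript quantifications of 33976 transcripts in the same order, with 1 transcript per gene ID. Estimated counts, deposited by the authors as read numbers per transcript, were not normalized and were often not whole (between 4593 and 14542 values per library lay more than 1e-9 from a whole number). The TPM values deposited by the authors (length-scaled transcript abundances) sum to 1000000 in each library, and the deposited lengths and effective lengths came with them. Estimated counts were rounded to whole numbers before any count test.

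Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, two-sided, TMM scaling, filterByExpr, no minimum fold) in R 4.3.3, with genotype as the only term and Benjamini-Hochberg adjustment at 0.05. After the filter 18385 genes were tested. Standard errors of log2 changes were computed as the size of the unshrunk log2 change divided by the square root of F, and 95% intervals used the moderated degrees of freedom. CPM values are counts per 1000000 assigned reads, given as mean ± SD over 2 libraries unless a single library is named. Gene lists with 3 or more tested members were tested with camera (limma 3.58.1, log2 CPM with a prior count of 2, preset inter-gene correlation of 0.01, two-sided), adjusted over 23 lists. Camera was repeated with the correlation estimated from the residuals. That version is limited to the residual degrees of freedom, which are few with 2 libraries against 2. It could thus hardly call any list, and a call lost there cannot be put down to correlation between genes alone. Fry was run as a self-contained test. With 2 libraries against 2, an exact permutation test of a single value cannot give a p below 0.333, so none was used.

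The files do not pair gene IDs with names, and the RefSeq gene table used here (assembly SLM_r2.1) holds no IDs of this kind. Pairs of ID and symbol were therefore written down from published tomato nomenclature as recalled, and each symbol was looked up in that table. A pair was used only if the symbol was on the chromosome that the ID names and at a like relative place in the order of that chromosome's genes, within 0.03. This check admitted 321 of 357 IDs. Of 335 pairs whose symbol the table holds, 95.8% passed, against 1.01% on average over 1000 random shuffles. A wrong pairing with a close neighbour would pass, so the names are less certain than the IDs. IDs that failed got no name and, apart from the SBP-box list, entered no list. The SBP-box list kept its 5 IDs, of which 2 passed; the symbols of the other 3 were not in the table.

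The SBP-box, meristem, flowering, floral organ identity, carpel and ovary, gibberellin, other microRNA-regulated and pollen and tapetum lists were fixed by ID before the data were examined. The lists on photosynthesis, pollen and style, auxin, cytokinin, ethylene, jasmonate, brassinosteroid and abscisic acid, cell division, further meristem and floral regulators, cell wall, flavonoids, defence, heat shock, trichomes and cuticle were written as IDs after the files had been opened and library totals seen, but before any fold change was computed. Planned lists based on descriptions (histones, ribosomal proteins, vascular markers, the MADS-box family) and the planned families of shared descriptions were not run, since no descriptions were used here. The planned search for miR156 sites was not run either, because no transcript sequences were used here. The SBP-box list takes its place, as planned, and no site is claimed for any gene.

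Genes were named by a rule set before the data were examined: every tested SBP-box ID, up to 4 members per list past the threshold or otherwise the member with the lowest p, any ID of the meristem, flowering, floral identity and gibberellin lists, and the 8 largest changes in each direction past the threshold with at least 2 CPM and no overlap of libraries. Other named genes are said to have been chosen after their values were seen. At most a pair of IDs without a name is printed per direction, so 1 SBP-box ID is described without its number.

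Alternatives covered the scaling, the low-count filter, DESeq2 1.42.0, limma on log2(TPM + 1), an effective-length offset, a replicate block, a minimum fold, and the omission of each library. In fits without 1 library, the lone library of a genotype is assumed to vary like the other genotype's pair. A crossed block, voom with library weights and thinning to the shallowest library were added after seeing the data. Figures were drawn with Matplotlib 3.10.9 from tables made with pandas 2.3.3 and NumPy 2.4.6 in Python 3.11.15.

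The edgeR and DESeq2 steps were tested on simulated data for the comparison of 156OE with MT on 18385 genes, with 200 genes changed and the real library sizes. Changed genes were drawn only from those with at least 50 reads at the mean library size. Both genotypes were given the same spread, whereas the real 156OE pair varied more than the MT pair. The shares recovered may therefore not hold for the real data. In edgeR, with each gene's spread as estimated, 28% of genes changed 2-fold, 92% changed 4-fold, 96% changed 8-fold and 100% changed 16-fold were recovered, and 34 unchanged genes were also called. With spread taken from the trend, those shares were 14%, 94%, 98% and 100%, and 0 unchanged genes were called. In DESeq2 the shares were 38%, 90%, 94% and 100% with 38 unchanged genes called, and with spread from the trend 14%, 90%, 96% and 100% with 1 called.

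Assigned reads numbered 11203505 and 9369713 in MT replicates 1 and 2, and 8440384 and 1685657 in 156OE replicates 1 and 2. A count of 3 reads, taken as the floor, was worth 0.268, 0.32, 0.355 and 1.78 CPM in that order. Floors and intervals of single libraries cover counting error only.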

Results

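The study addresses how gibberellin and the miR156-SBP module act on floral meristems and fruit patterning, and the deposited comparison is between floral apices and closed buds of miR156-overexpressing tomato (156OE) and of MT. There were 2 libraries per genotype. The MT libraries held 11203505 and 9369713 assigned reads and the 156OE libraries 8440384 and 1685657. At least 1 read was assigned to 22566 and 22283 of the 33976 genes in MT and to 22401 and 19846 in 156OE. Log2 CPM values correlated at 0.987 across genes between the MT replicates and at 0.917 between the 156OE replicates. 156OE replicate 2 also correlated least with MT, at 0.921 and 0.906, against 0.964 and 0.967 for 156OE replicate 1. Counts differed by more than sampling noise in both replicate pairs, with a chi-square per degree of freedom of 4.12 in MT and 21.1 in 156OE.

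Most of the listed SBP-box IDs had lower transcript levels in 156OE. The SBP-box family of transcription factors contains the known targets of miR156. No members beyond the list were examined, and the symbols of 3 listed IDs could not be checked. All 5 IDs of the list were measured, and 4 of them fell in edgeR's test when adjusted over the list alone. Solyc03g114850 had 343 ± 32.1 CPM in MT and 98.6 ± 15.3 CPM in 156OE (SD, n = 2), a log2 change of -1.70 ± 0.13 (SE; edgeR adjusted p = 0.000212 over the list alone). Solyc10g078700 fell from 65.3 ± 3.01 CPM in MT to 21.33 and 14.24 CPM in the 156OE libraries, a log2 change of -1.74 ± 0.17 (edgeR adjusted p = 0.00029 over the list alone). For SBP3 (Solyc10g009080) the values were 25.8 ± 3.69 and 5.33 ± 4.19 CPM, a log2 change of -1.96 ± 0.40 (edgeR adjusted p = 0.0053 over the list alone), which was -3.25 without 156OE replicate 1 and -1.63 without 156OE replicate 2. The fourth ID, whose symbol was not checked, had 137 ± 9.85 and 72.1 ± 18.9 CPM, a log2 change of -0.83 ± 0.16 (edgeR adjusted p = 0.00529 over the list alone). In each of these 4, both 156OE libraries lay below both MT libraries. CNR (Solyc02g077920), known for its role in fruit ripening, was not past the threshold, with 5.67 ± 1.33 CPM in MT, 4.74 CPM in 156OE replicate 1 and no read in 156OE replicate 2, where the floor is 1.78 CPM.

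Adjusted over all 18385 genes, 0 of the 5 SBP-box IDs passed in edgeR, the lowest adjusted p being 0.132, while DESeq2 placed 4 of them under 0.05. As a list the SBP-box IDs were lower than other genes (camera adjusted p = 9.9e-05, median log2 change -1.70). That call was lost with an estimated correlation (adjusted p = 0.877, unadjusted p = 0.153). With few residual degrees of freedom, that setting could hardly call any list.

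**Figure D1:**
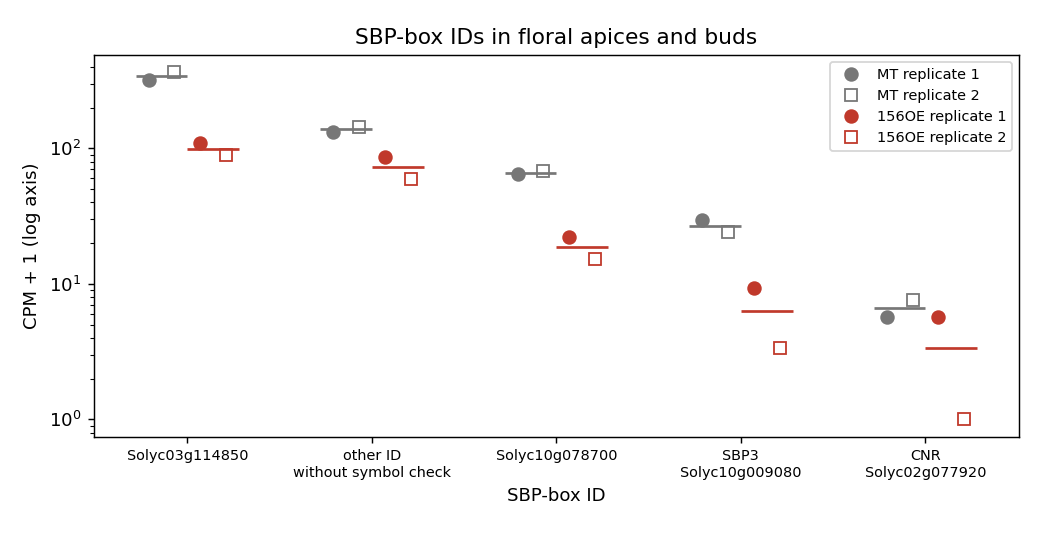
CPM + 1 on a log axis for the 5 SBP-box IDs in each library; circles are replicate 1, squares replicate 2, grey MT and red 156OE, and lines mark the mean of 2 libraries per genotype. In 4 IDs both 156OE libraries sit below both MT libraries, and CNR has no read in 156OE replicate 2.

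Across all genes, edgeR called 1 gene higher and 0 lower in 156OE, with 2095 genes at an unadjusted p under 0.05. The gene called was Solyc07g006570, at 13.3 and 13.98 CPM in the MT libraries and 117.3 and 109.75 CPM in the 156OE libraries, a log2 change of 3.15 ± 0.12 (SE; edgeR adjusted p = 0.0209). This gene was not called in edgeR with a replicate block or a crossed block (lowest adjusted p of any gene 0.0959 and 0.108). Nor was it called with limma on log2(TPM + 1) (lowest adjusted p 0.187). DESeq2 called 145 genes higher and 63 lower. Without 156OE replicate 2, edgeR called 650 higher and 429 lower; without 156OE replicate 1, it called 1532 higher and 466 lower; without either MT library it called 0. Of the genes called against the same MT pair, 221 were higher and 121 lower with both 156OE libraries, and 87 went in opposite directions. Independent lists of these sizes would share 46.5, 10.8 and 48.6 genes, and 20 simulated data sets with no effect and the spread of the MT pair gave 0 in each class. With the spread of the 156OE pair given to the 156OE libraries, a simulation chosen after seeing the data gave 166 to 246 higher, 190 to 247 lower and 269 to 360 opposite, so the observed counts lie within or below these ranges. Lower and opposite calls were fewer in the data than in every draw of that simulation. In every draw, opposite calls outnumbered the higher calls and also the lower calls, whereas in the data they were fewer than either. The data thus leaned further to shared directions than this simulation, which also kept the MT pair common to both fits. Since it made more lower and opposite calls than the data, its spread was not matched to them. It cannot tell how much of the sharing exceeds replicate noise. Part of the sharing may come from the shared MT libraries, which cannot be split. Of the 145 and 63 genes called by DESeq2, 118 and 61 were among those shared calls. In 46% of tested genes the libraries of the genotypes did not overlap. Chance gives 33.3% only where all libraries vary alike. The 156OE pair varied more than the MT pair (common dispersion 0.0978 against 0.00672), so this comparison decides nothing about genotype.

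Among flowering and inflorescence regulators, 2 of 10 tested genes fell when adjusted over the list alone and 0 when adjusted over all genes in edgeR. FA (FALSIFLORA, Solyc03g118160), the tomato LEAFY gene, had 110 ± 11.7 CPM in MT and 53.7 ± 18.1 CPM in 156OE, a log2 change of -0.92 ± 0.20 (edgeR adjusted p = 0.0284 over the list alone, 0.295 over all genes); DESeq2 gave it an adjusted p of 0.0334. MBP20 (Solyc02g089210), a FRUITFULL-type MADS-box gene, had 34.1 ± 0.998 and 20.6 ± 2.33 CPM, a log2 change of -0.63 ± 0.14 (edgeR adjusted p = 0.0284 over the list alone). The flowering repressor SP (Solyc06g074350) had 40.3 ± 3.92 CPM in MT and 39.2 ± 0.0441 CPM in 156OE, and FUL1 (Solyc06g069430) 63.4 ± 2.05 and 75.8 ± 1.84 CPM. Both calls over the list alone were lost without MT replicate 1 and without MT replicate 2, where the 156OE pair alone gave the spread. The log2 changes were then -0.83 and -1.05 for FA and -0.66 and -0.6 for MBP20. The list as a whole had a camera adjusted p of 0.344.

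No meristem and boundary regulator of 12 tested passed in edgeR, either over all genes or over the list alone, and the list had a camera adjusted p of 0.44. WUS (Solyc02g083950), which maintains the stem cell pool, had 15.2 ± 3.44 CPM in MT and 13.5 ± 0.265 CPM in 156OE, with a 95% interval of the log2 change from -0.73 to 0.51. Its antagonist CLV3 (Solyc11g071380) had 3.95 ± 0.602 and 4.62 ± 0.666 CPM, and the receptor kinase gene FAB (Solyc04g081590) had 72.1 ± 1.12 and 51.9 ± 13 CPM. The KNOX gene TKN2 (Solyc02g081120) had 131 ± 18.1 and 149 ± 29.0 CPM. In the carpel, ovary and organ polarity list, 1 of 4 tested genes rose when adjusted over the list alone. This was CRCa (Solyc01g010240), a YABBY gene of the CRABS CLAW type, at 0.9 ± 0.368 CPM in MT and 4.98 ± 1.17 CPM in 156OE. Its log2 change was 2.56 ± 0.45 (edgeR adjusted p = 0.00801 over the list alone, 0.262 over all genes). Over the list alone the call was lost without MT replicate 1 and without MT replicate 2, at log2 changes of 3.03 and 2.19. That list was higher in camera (adjusted p = 0.0364; adjusted p = 0.877 with an estimated correlation), and its call was also lost without MT replicate 1 (camera adjusted p = 0.0518), without 156OE replicate 1 (0.388) and with no low-count filter (0.901).

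Of the floral organ identity MADS-box genes, 9 of 9 tested members had a lower value in 156OE replicate 2 than in replicate 1. No member passed in edgeR over all genes or over the list alone, and the list's camera adjusted p was 0.531. The estimated correlation between its members was 0.937, far above the preset 0.01, and gave a camera adjusted p of 0.904. The other camera values of this paragraph used the preset correlation. Relative to the MT mean, the B-class gene TAP3 (Solyc04g081000) was 2.54 times as high in 156OE replicate 1 and 0.232 times in replicate 2. For the C-class gene TAG1 (Solyc02g071730) these ratios were 1.97 and 0.257, for the SEPALLATA-type genes TM5 (Solyc05g015750) 1.60 and 0.583, and for EJ2 (Solyc03g114840) 1.49 and 0.542. The counts behind the lowest of these in 156OE replicate 2 were 5 reads for TAG1 and 6 for TAP3. Without 156OE replicate 2 the list was higher (camera adjusted p = 0.00536), with 5 members called over all genes, and without 156OE replicate 1 it was lower (camera adjusted p = 0.00159), with 5 called. LIN (Solyc04g005320), another SEPALLATA-type gene, was below MT in both, at 0.683 and 0.265 times the MT mean, and did not pass (edgeR adjusted p = 0.441 over all genes).

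GA2ox4 (Solyc07g061720), which encodes a gibberellin-inactivating oxidase, had 6.22 ± 0.797 CPM in MT, 36.97 CPM in 156OE replicate 1 and 4.75 CPM in replicate 2, and GA2ox5 (Solyc07g061730) 8.94 ± 0.111, 34.83 and 6.53 CPM. Over the list alone their edgeR adjusted p was 0.0891, and without 156OE replicate 2 both were called higher over all genes. The biosynthetic gene GA20ox1 (Solyc03g006880) had 3.89 ± 0.816 CPM in MT and 6.05 ± 1.84 CPM in 156OE. Of 4 tested genes of biosynthesis and inactivation and 5 of perception and signalling 0 passed in edgeR, with camera adjusted p of 0.434 and 0.491. Without 156OE replicate 2 the first of these lists was higher (camera adjusted p = 0.00267), and without 156OE replicate 1 it was not called (0.75). The DELLA gene PROCERA (Solyc11g011260) had 208 ± 22 CPM in MT and 177 ± 41.7 CPM in 156OE, the receptor gene GID1a (Solyc01g098390) 88.8 ± 1.09 and 83.4 ± 5.45 CPM, and SLY1 (Solyc04g078390) had the lowest p of its list, at 44.3 ± 15.4 and 70.4 ± 10.4 CPM.

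**Figure D2:**
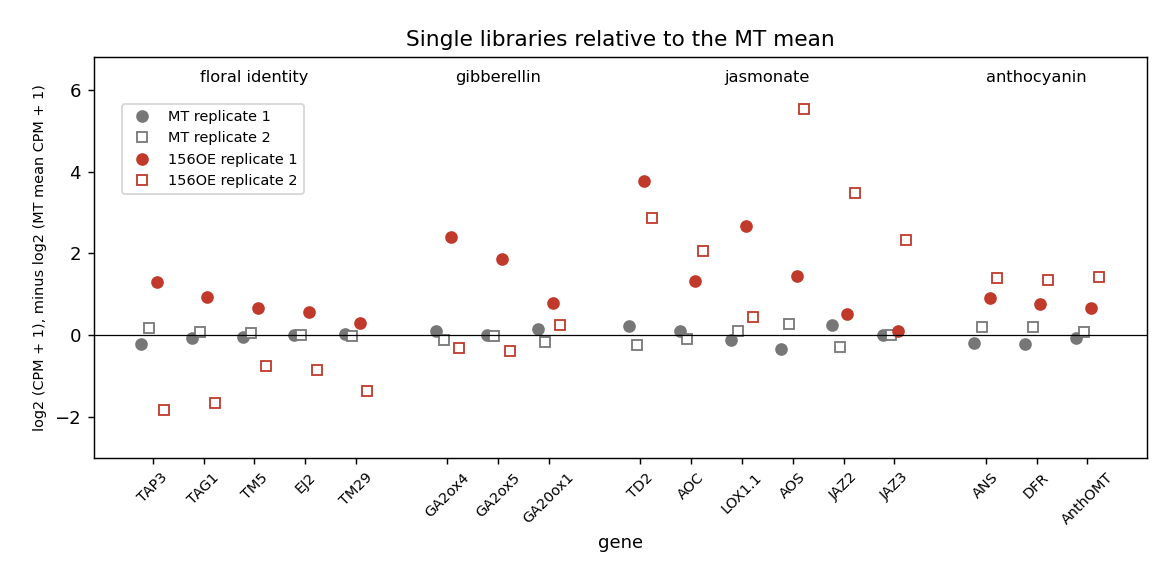
Log2 of CPM + 1 in each library minus log2 of the MT mean CPM + 1, for genes of 4 lists; circles are replicate 1, squares replicate 2, grey MT and red 156OE. The 5 floral identity genes drawn lie above the MT mean in 156OE replicate 1 and below it in 156OE replicate 2, whereas TD2 lies above it in both. These 5 are a selection from 9 tested members, and not all members switched sides. LIN, not drawn, was below MT in both 156OE libraries. TM6 (Solyc02g084630), also not drawn, had log2 changes of 0.51 without 156OE replicate 2 and 0.07 without 156OE replicate 1.

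Jasmonate genes were higher in 156OE as a list of 16 tested members (camera adjusted p = 0.000344, median log2 change 1.04; adjusted p = 0.877 and unadjusted p = 0.0464 with an estimated correlation). The estimated correlation of the list was -0.0573, below the preset 0.01, so correlation between members cannot account for the higher p in that setting. Against MT the list's median log2 difference was 0.40 in 156OE replicate 1 and 1.05 in replicate 2. Over the list alone, 3 members rose in edgeR, and over all genes 0 did. TD2 (Solyc09g008670), a jasmonate-inducible threonine deaminase, had 8.08 ± 2.07 CPM in MT and 93.8 ± 40.3 CPM in 156OE, a log2 change of 3.63 ± 0.32 (edgeR adjusted p = 0.0013 over the list alone, 0.149 over all genes). Chosen after their values were seen, the allene oxide cyclase gene AOC (Solyc02g085730) had 149 ± 16.1 and 500 ± 173 CPM (edgeR adjusted p = 0.015 over the list alone) and JAR1 (Solyc10g011660), which conjugates jasmonate to isoleucine, 16.1 ± 0.589 and 26.3 ± 1.9 CPM (edgeR adjusted p = 0.016 over the list alone). The calls over the list alone were lost for AOC and JAR1 without MT replicate 1, at log2 changes of 1.97 and 0.75. They were also lost without MT replicate 2, at 1.75 and 0.83, against 1.86 and 0.8 with all libraries. DESeq2 called TD2 and AOC over all genes. Other members, also chosen after their values were seen, had unequal values in the 156OE libraries: AOS (Solyc04g079730) was 71.1 times the MT mean in 156OE replicate 2 and 3.65 times in replicate 1, JAZ2 (Solyc12g009220) 11.6 and 1.44 times, and LOX1.1 (Solyc08g014000) 1.39 and 6.74 times.

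The flavonoid and anthocyanin list was higher in camera (14 tested, adjusted p = 0.0113; adjusted p = 0.877 with an estimated correlation), with 0 members past the threshold in edgeR. Its lowest p was that of ANS (Solyc08g080040), anthocyanidin synthase, at 11.7 ± 2.44 CPM in MT and 27.7 ± 6.99 CPM in 156OE. The call was lost without 156OE replicate 2 (camera adjusted p = 0.119) and without MT replicate 1 (0.0518). The cell wall list was also higher (11 tested, camera adjusted p = 0.0238; adjusted p = 0.877 with an estimated correlation), and its call was lost without 156OE replicate 1 (0.107). The estimated correlation of the cell wall list was -0.0984, below the preset 0.01, so correlation cannot account for its higher p in that setting. The expansin gene EXP2 (Solyc06g049050) of this list rose from 9.05 ± 0.577 to 20.6 ± 5.6 CPM (edgeR adjusted p = 0.0172 over the list alone). The call of EXP2 was lost without MT replicate 1 and without MT replicate 2, at log2 changes of 1.35 and 1.22 against 1.3 with all libraries.

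The remaining lists were not past the threshold in camera. Within them, edgeR adjusted over the list alone called LOG6 (Solyc10g084150), a cytokinin-activating enzyme gene, higher at 36.0 ± 9.86 CPM against 19.7 ± 0.339 CPM in MT (adjusted p = 0.0118). It called the ACC oxidase gene ACO6 (Solyc02g036350) lower at 16.8 ± 1.44 against 36.7 ± 0.223 CPM (adjusted p = 0.0251), and DESeq2 gave ACO6 an adjusted p of 0.0464 over all genes. In the same list it called EIL4 (Solyc06g073730), an EIN3-like gene chosen after its value was seen, higher at 46.6 ± 1.22 against 30.1 ± 0.0507 CPM (adjusted p = 0.0263). The MADS-box gene FYFL (Solyc03g006830) was lower at 2.25 ± 0.668 against 9.94 ± 0.327 CPM (edgeR adjusted p = 0.03 over the list alone), with 3 reads in 156OE replicate 2, and so was the HSP90 gene Solyc06g036290 at 7.88 ± 3.6 against 21.8 ± 0.348 CPM (edgeR adjusted p = 0.0399 over the list alone). LAT56 (Solyc03g058910), a pollen-expressed pectate lyase gene, fell from 5.37 ± 1.11 to 1.42 ± 0.334 CPM (edgeR adjusted p = 0.0179 over the list alone), with 2 reads in 156OE replicate 2, below its floor of 3. Without MT replicate 1 and without MT replicate 2 these calls over the list alone were lost, with the spread then taken from the 156OE pair alone. The log2 changes in those fits were 0.98 and 0.95 for LOG6 (0.98 with all libraries), -1.06 and -1.04 for ACO6 (-1.07) and 0.72 and 0.72 for EIL4 (0.71). For FYFL they were -1.96 and -2.02 (-1.96), for the HSP90 gene -1.35 and -1.31 (-1.28) and for LAT56 -1.55 and -1.97 (-1.75). The call of LAT56 was also lost without 156OE replicate 1, at -1.99. No member passed over the list alone in the auxin list, where LAX4 (Solyc10g076790), an auxin influx carrier gene, had 52.0 ± 4.78 CPM in MT and 24.7 ± 6.35 CPM in 156OE.

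Camera adjusted p was 0.434 for cytokinin metabolism (5 tested), 0.44 for auxin (36), 0.924 for ethylene (17), 0.66 for further meristem, floral and ovary regulators (29) and 0.67 for heat shock (9). For pollen, anther and style markers it was 0.434 (3), for photosynthesis and leaf markers 0.44 (17), for cell division 0.491 (15) and for brassinosteroid and abscisic acid 0.44 (10). It was 0.813 for other microRNA-regulated factors (4), 0.574 for defence (7), 0.491 for trichome markers (3) and 0.44 for cuticle markers (4). Lowest p in the lists without a call belonged to RBCS3 (Solyc02g085950), a Rubisco small subunit gene, at 134 ± 3.53 CPM in MT and 353 ± 168 CPM in 156OE, to krp1 (Solyc09g091780) in cell division at 57.5 ± 2.85 and 75.9 ± 7.55 CPM, to AREB1 (Solyc04g078840) at 12.9 ± 2.03 and 19.5 ± 1.57 CPM and to AP2c (Solyc02g093150) at 14.1 ± 1.3 and 16.7 ± 5.1 CPM. In defence it was CHI17 (Solyc02g082930), at 5.75 ± 1.07 and 9.84 ± 0.345 CPM, among trichome markers MTS1 (Solyc01g105890), at 2.37 ± 0.182 and 10.1 ± 6.63 CPM, and among cuticle markers CD1 (Solyc11g006250), at 157 ± 6.14 and 122 ± 17.7 CPM. Without 156OE replicate 2 the photosynthesis list was higher (camera adjusted p = 0.000369), with 6 members called higher and 0 lower over all genes, while without 156OE replicate 1 it was not called (0.317), with 1 member higher and 4 lower. RBCS3 was called higher in both of these fits. The list of pollen and tapetum markers kept 1 ID after the check of names, a pollen gene that was not tested, so it held no tapetum marker.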

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

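The replicate numbers do not pair the samples by any label, and deviations of same-numbered libraries correlated at -0.251 across genes. Genes higher and lower in 156OE numbered 1 and 0 in the reported edgeR fit, 57 and 28 with no filter beyond 1 read, 145 and 63 with DESeq2, 0 and 0 with limma on log2(TPM + 1), and 0 and 0 with a replicate block. Leaving out 1 library gave 0 to 1532 higher and 0 to 466 lower. With alternatives chosen after seeing the data, voom with library weights gave 23 and 3 and thinning to the shallowest library 1 and 0. The crossed pairing gave 0 and 0. Other scalings, the stricter filter, the length offset and the minimum fold gave 1 and 0. In the fits without a 156OE library the spread came from the MT pair alone (common dispersion 0.00667, against 0.0426 with all libraries). In the fits without an MT library it came from the 156OE pair alone. Beyond this, the cause of these differences was not tested.

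SBP-box IDs lower over all genes numbered 0 in the reported fit, 2 with no filter, 4 with DESeq2, 2 with voom weights and 0 to 5 with 1 library left out; over the list alone every alternative run gave 3 to 5. Their camera adjusted p was 4.42e-05 to 0.000953 with 1 library left out, and 0.877 with an estimated correlation; fry, which tests a list against no change, gave an adjusted p of 0.197. Lists higher and lower numbered 4 and 1 as reported, 0 and 0 with an estimated correlation, 2 and 0 with fry, and 2 to 6 and 1 to 2 with 1 library left out. The 2 lists called by fry were jasmonate and cell wall, each at a fry adjusted p of 0.0148. With an estimated correlation hardly any list could be called, given the few residual degrees of freedom. The replicate block changed no list count. The floral identity list ranged from an adjusted p of 0.00159 to 0.6 with 1 library left out and turned direction.

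Of 63 genes followed through the settings, not all of which are named in the text, 16 had both signs. In 8 of them the reported change exceeded its SE or the alternative passed the threshold, by log2 change with 1 library left out: TAP3 -1.91 to 1.36, TAG1 -1.77 to 0.99, EJ2 -0.70 to 0.58, GA2ox4 -0.21 to 2.57, GA2ox5 -0.27 to 1.97, GID1b1 -0.06 to 1.13, NCED1 -0.23 to 3.41 and WRKY40 -1.62 to 2.46 (-0.81 with voom weights). Of 18 genes called over a list alone, 5 were called with each library left out. Planned site mismatches and description families were not run. The 1685657 reads of 156OE replicate 2 limit what low genes can show, with a floor of 1.78 CPM.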

Other observations

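Apart from GID1b1, the genes of this paragraph were chosen after their values were seen. WRKY40 (Solyc06g068460) had 30.2 ± 7.12 CPM in MT, 9.83 CPM in 156OE replicate 1 and 147.7 CPM in replicate 2, and NCED1 (Solyc07g056570), a key enzyme gene of abscisic acid synthesis, 7.55 ± 0.561, 6.4 and 71.19 CPM. The receptor gene GID1b1 (Solyc09g074270) was 0.956 and 1.93 times the MT mean in the 156OE libraries. The anthocyanin genes DFR and AnthOMT, by contrast, were above both MT libraries in both 156OE libraries, at 31.99 and 48.65 CPM and at 21.92 and 37.38 CPM, with edgeR adjusted p of 0.0547 over the list alone. fsm1 (Solyc10g052470), a MYB-like gene of early fruit growth, had 7.96 ± 0.522 CPM in MT and 2.49 ± 0.165 CPM in 156OE (edgeR adjusted p = 0.0399 over the list alone). That call was lost without MT replicate 1, without MT replicate 2 and without 156OE replicate 1, at log2 changes of -1.65, -1.51 and -1.55. The ID before the gene called by edgeR, Solyc07g006560, had 16.33 and 18.04 CPM in MT and 101.18 and 70.6 CPM in 156OE (log2 change 2.42 ± 0.16, SE; edgeR adjusted p = 0.132). Whether reads of these consecutive IDs are shared between similar copies was not tested.

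The tests on a mislabelled library, on library scaling and on floral organs were chosen after the values they measure were seen. 156OE replicate 2 lies apart from the other 3 libraries, and no biological explanation of this was tested. Lower depth was argued against as the whole cause. Thinned to the same total, 156OE replicate 1 kept a mean correlation of 0.95 with the MT libraries, against 0.913 for 156OE replicate 2. The SD over 20 draws was 0.000651, which covers only the resampling of reads. Unthinned, 156OE replicate 1 had a mean correlation of 0.965, so lower depth can account for part of the gap. A mislabelled MT library was argued against by the SBP-box IDs, whose median log2 difference from MT was -1.99 in this library, with all 5 lower. Loss of long or short transcripts was argued against by a Spearman rho across genes of -0.0428 between transcript length and the difference of the 156OE libraries, although rho was -0.184 against the MT mean and 0.297 between the MT libraries. What sets this library apart stays open, and a difference in the plants or in handling is among the untested explanations.

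Floral organ identity genes lay lower in 156OE replicate 2 than in replicate 1, in 9 of 9 members. Library scaling does not account for this, as the list's median difference was -1.28 (SE 0.36) on the log2 scale against -0.02 over all tested genes. That SE takes the members as independent, though their estimated correlation was 0.937, so it is likely too small. Counting noise was argued against by thinning, in which the lowest median of the list was -0.13 in 20 draws. A candidate explanation is that the tissue of this library held fewer or younger floral organs. It was assumed, not tested, that such a shift would leave the median of the meristem list in place. That median also lay low, at -0.34, with 11 of 12 members lower in 156OE replicate 2 than in replicate 1. It was at percentile 0.69 among 10000 random lists matched on expression. Genes of the meristem list varied together (estimated correlation 0.589), which random lists do not keep, so the percentile cannot decide. The candidate explanation cannot be told apart from a change that also covers meristem genes. Medians of other lists also differed between the 156OE libraries, but these differences were not tested. They were -1.32 for gibberellin biosynthesis and inactivation, -0.78 for pollen, anther and style, -0.73 for cytokinin and -0.59 for cuticle. They were -0.57 for other microRNA-regulated factors, -0.40 for photosynthesis and for SBP-box IDs, 0.67 for flavonoids and 1.58 for trichomes. The gibberellin, cuticle and microRNA-regulated lists held 4 tested genes each, and the pollen and trichome lists 3. Lists not named here had smaller medians. The explanation stays open.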
